A study of Homo sapiens with 44 samples.

How the data were processed

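RNA-seq was analysed from 44 libraries of H9 cells at days 0, 6, 7, 9 and 19 of differentiation, in 22 groups of 2. Per the labels, RNA was taken with Trizol, treated with DNase and made into libraries with a standard Illumina preparation of polyadenylated RNA, and treatment began at day 1 for myriocin and at day 3 for vehicle, lipids and doxycycline. The authors' notes give base calling with CASAVA 1.8.2, quantification with Salmon 0.8.2 against GRCh38.p12 and GENCODE 29, and DESeq2 without a version. Strandedness and further options are not stated. The deposited file of each library holds 205870 transcripts with estimated counts (Salmon's NumReads) and TPM. A deposited series table in TPM equals the sums of the library files per gene to within 0.001, so it was used for this check alone. No table held columns of another series, and no 2 libraries were identical.

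Estimated counts were summed to 58294 genes and rounded. Totals ranged from 18.9 to 48.8 M (median 29.6 M), with 28368 to 38010 genes with reads, 4.22% to 13.4% of counts from mitochondrially encoded genes and 6.34% to 14.21% from the 10 genes with most counts. Groups were read from the labels and no library was left out. The comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. There was 1 mean per group and 1 fit per experiment, and p-values were adjusted with the Benjamini-Hochberg method over the genes tested in each of 25 comparisons at a threshold of 0.05. In 5 comparisons the difference between the genotypes in the response to a treatment was tested. The SE is the absolute log2 fold change divided by the square root of F. For 28 gene lists, written beforehand from textbook knowledge, members were counted and camera of limma 3.58.1 compared each list with the other genes, with a preset correlation of 0.01 and, as an alternative, an estimated correlation.

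Named genes followed a rule. NR2F1, NR2F2 and SPTLC1 were followed throughout. The genes of largest rise and fall were taken among those past the threshold with a mean log2 CPM of at least 1 and, outside tests of a difference of responses, both libraries of a group beyond both of the other. There were 6 each way for the 6 main comparisons and 3 for the others. Up to 3 members per list were added for the main comparisons and up to 2 members of lists called by camera for the others. Clone names, pseudogenes, loci without a name and sex-linked markers were passed over. Some results are not reported here. Not every gene the rule gives is printed, and those whose calls did not depend on a single library were preferred, a choice made after the values were seen. Principal components used the 2000 most variable genes on log2 CPM with a prior count of 2.

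The test was checked on simulated data for 6 comparisons. Counts were drawn from a negative binomial distribution with the mean and dispersion of each gene, equal in all groups but for 200 changed genes. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 37.3%, 86.6% and 100% for the undifferentiated cells, 53.7%, 77.6% and 98.5% for myriocin at day 6 and 29.9%, 70.1% and 93.9% for 1-deoxysphingosine. The values were 62.7%, 83.6% and 98.5% for myriocin at day 19, 41.8%, 62.7% and 93.9% for doxycycline at day 9, and 16.4%, 56.7% and 80.3% for the difference of the doxycycline responses. False calls made up 18.6%, 10%, 7.2%, 10.4%, 4.3% and 3.8% of the calls in that order, above the nominal 5% in 4 of the 6. Of 200 random lists per comparison camera gave 5 to 8 a p under 0.05 with the preset correlation and 0 to 2 with an estimated correlation. Genes were drawn independently of each other. The check therefore cannot show how often the preset correlation gives false calls for lists of correlated genes. Alternatives were a fit of all 44 libraries, RLE factors, no low count filter, the Wald test of DESeq2 1.42.0, a transcript length offset, a replicate block and each library left out in turn. Fits without mitochondrially encoded genes and of the day 9 libraries alone were chosen after seeing the data. Where a library is left out, the lone library of its group is assumed to vary like the other groups. No group has enough libraries for a test of outliers or of other splits of the samples.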

Results

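Gene expression was measured by RNA-seq of polyadenylated RNA in 44 libraries of H9 human embryonic stem cells (ESC), an established line, and of cells made from them with a cardiomyocyte differentiation protocol. The libraries formed 22 groups of 2. Unedited cells (WT) were set against cells labelled as lacking NR2F1 and NR2F2 (DKO), the genes of the nuclear receptors COUP-TFI and COUP-TFII. The groups covered undifferentiated cells at day 0, cells given vehicle or myriocin and collected at day 6 or 19, and cells given vehicle, 1-deoxysphingosine or D-erythro-sphingosine and collected at day 9. The remaining groups carried a doxycycline-inducible SPTLC1 with the C133W change and were grown with or without doxycycline to day 7 (WT) or day 9 (WT and DKO). Myriocin inhibits serine palmitoyltransferase, the first enzyme of sphingolipid synthesis. SPTLC1 encodes a subunit of that enzyme. C133W is found in hereditary sensory and autonomic neuropathy and lets the enzyme use alanine, which gives 1-deoxysphingolipids. Lipids were not measured here. 1-deoxysphingosine differs from sphingosine by the missing hydroxyl at carbon 1. Doses were not in the labels. The lipids and their vehicle share a start at day 3, but myriocin began at day 1 and its vehicle at day 3, so each myriocin result is confounded with the start of treatment. The stated purpose was to examine target genes of NR2F1 and NR2F2 under these treatments. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Changes are log2 fold changes ± SE and levels are CPM (counts scaled to library size within a fit) ± SD, with n = 2 libraries per group throughout. The SE comes from the F test and falls short of counting error for some genes with few reads. Where counting error exceeded it by over 1.5 times, the 95% counting interval stands in brackets in its place. Counting intervals and floors cover counting error only. Beside each gene list stand the members called over all genes tested, those called when adjusted over the list alone, and the test against the other genes with camera, whose p is adjusted also with an estimated correlation. The level minimum, used to rank changes, was a mean log2 CPM of 1 over the groups compared, which leaves out many genes near 0 in a group.

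The undifferentiated and differentiated WT vehicle cells were compared first, to place the later results. From day 0 to day 9 cardiac genes appeared and pluripotency genes fell. Cardiac progenitor genes rose (17 of 17 higher, 17 adjusted over the list alone, camera adjusted p = 3.44e-12, p = 0.0014 with an estimated correlation), among them GATA6 (10.43 [9.5 to 11.69]) and HAND2 (10.66 [9.73 to 11.92]). Sarcomere and calcium-handling genes rose (24 of 24 higher, 24 adjusted over the list alone, camera adjusted p = 2.46e-15, p = 0.0279 with an estimated correlation), with the atrial light chain gene MYL7 up by 10.27 ± 0.19. Pluripotency genes fell (17 of 17 lower, 17 adjusted over the list alone, camera adjusted p = 2.73e-10, p = 0.0014 with an estimated correlation). L1TD1 changed by -6.07 ± 0.17. Genes of other cell types also rose by day 9. They include the epicardial list (10 of 11 higher, 10 adjusted over the list alone, camera adjusted p = 7.94e-06, p = 0.00847 with an estimated correlation) and the endoderm list (15 of 17 higher and 1 lower, 17 adjusted over the list alone, camera adjusted p = 3.83e-07, p = 0.029 with an estimated correlation). AFP, the fetal liver protein, changed by 6.41 ± 0.17. From day 9 to day 19 sarcomere genes rose further (23 of 24 higher and 1 lower, 24 adjusted over the list alone, camera adjusted p = 2.2e-10, p = 0.0952 with an estimated correlation). The ventricular genes changed, MYH7 by 7.54 ± 0.16 and MYL2 by 11.57 ± 0.25. Epicardial genes fell (10 of 11 lower, 10 adjusted over the list alone, camera adjusted p = 2.59e-05, p = 0.0138 with an estimated correlation). WT1 changed by -5.63 ± 0.21. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 18273 of 27279 genes for day 9 against day 0 and 16923 for day 19 against day 9. Camera called 21 of 28 lists, 10 with an estimated correlation, and 12 of 28 lists, 3 with an estimated correlation, in that order. Both comparisons cross experiments. The first principal component placed the 24 libraries of days 7 and 9 between 16.5 and 78.3 and the 20 libraries of days 0, 6 and 19 between -91.1 and -20.3, so part of a stage difference cannot be told apart from a difference between experiments.

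The edited genes and SPTLC1 were examined in every library. NR2F1 (ENSG00000175745.12, chromosome 5, 93583224 to 93594615, GRCh38) was not low in the differentiated libraries labelled DKO. In vehicle cells it stood at 26.5 ± 1.5 CPM in DKO-labelled against 0.49 ± 0.18 CPM in WT cells at day 6, at 262 ± 44 against 43.5 ± 3.9 CPM at day 9, and at 8.85 ± 0.67 against 0.489 ± 0.032 CPM at day 19. The fold changes were 5.73 ± 0.24, 2.59 ± 0.24 and 4.16 ± 0.21 (edgeR adjusted p = 3.45e-12, 4.54e-06 and 9.17e-10). NR2F2 (ENSG00000185551.14, chromosome 15, 96325938 to 96340263) was higher likewise, by 5.14 ± 0.13, 1.71 ± 0.17 and 4.94 ± 0.12 (edgeR adjusted p = 8.5e-15, 9.09e-06 and 7.56e-13). In undifferentiated cells both genes were near the detection limit. NR2F1 had 3 counts over both DKO-labelled libraries and 27 over both WT libraries, a ratio of 7.61 with a 95% counting interval of 2.34 to 39.2, and NR2F2 stood at 0.206 ± 0.17 against 0.897 ± 0.054 CPM. In the inducible lines without doxycycline at day 9 neither gene differed past the threshold (NR2F1 -0.55 ± 0.26, edgeR adjusted p = 0.105, NR2F2 0.04 ± 0.14, edgeR adjusted p = 0.855). In differentiated cells total transcript therefore did not follow the genotype label, and the libraries are called DKO-labelled throughout. The files give no reads over the edited bases, so gene-level counts check the label only in part. One transcript did separate the labels. NR2F1-205, with 4 exons between 93585024 and 93594072 on chromosome 5, had 16 to 222.9 reads in each of the 14 WT libraries of days 7 and 9 and none in the 20 DKO-labelled libraries, but also none in the other 10 WT libraries, where NR2F1 was low. This form was picked after its values were seen. SPTLC1 (ENSG00000090054.14, chromosome 9, 92000087 to 92115384) rose with doxycycline, by 2.85 ± 0.12 in WT cells at day 7, 1.06 ± 0.12 in WT cells at day 9 and 1.1 ± 0.12 in DKO-labelled cells at day 9 (edgeR adjusted p = 7.99e-07, 0.000417 and 0.0222). Counts do not tell the induced C133W transcript from the endogenous one.

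**Figure D1:**
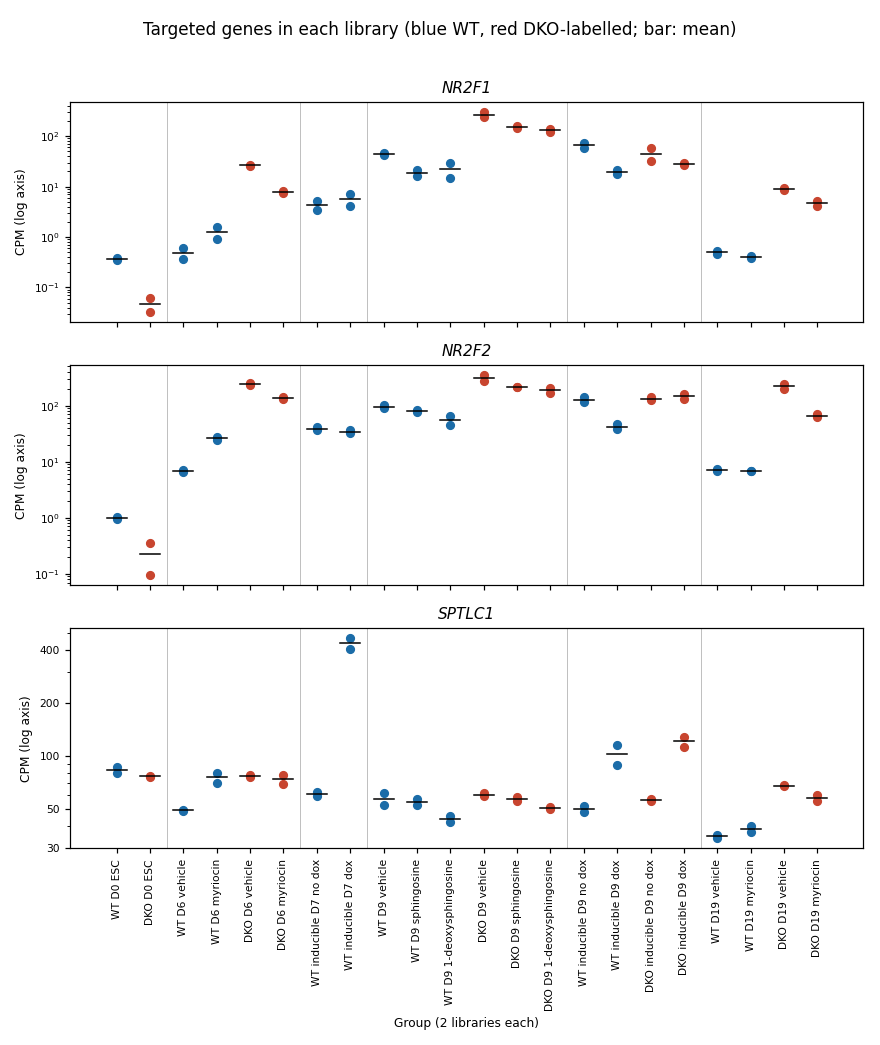
Level of NR2F1, NR2F2 and SPTLC1 in CPM (log axis), 1 point per library, by group and day, with WT and DKO-labelled libraries in separate colours. Scaled over all 44 libraries, NR2F2 averaged 246 ± 15 CPM in DKO-labelled and 6.9 ± 0.31 CPM in WT vehicle libraries at day 6, and SPTLC1 439 ± 42 CPM in WT doxycycline libraries at day 7.

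Undifferentiated DKO-labelled cells differed from WT cells in lipid and stress genes. Cholesterol synthesis genes were higher (24 of 25 higher, 24 adjusted over the list alone, camera adjusted p = 5.26e-22, p = 0.42 with an estimated correlation). INSIG1, the sterol-regulated brake on this pathway, changed by 1.78 ± 0.09 and the sterol oxidase gene MSMO1 by 1.21 ± 0.08. Integrated stress response genes were higher (15 of 23 higher, 20 adjusted over the list alone, camera adjusted p = 1.01e-10, p = 0.42 with an estimated correlation). CHAC1 changed by 2.06 ± 0.19 and ATF4 by 0.76 ± 0.07. Above the level minimum, falls were largest in NLRP2 (-8.89 [-9.71 to -8.20], from 111 ± 18 to 0.233 ± 0.048 CPM), ZNF93 (-6.56 ± 0.22) and ZNF615 (-5.87 ± 0.26), and rises in LINC01487 (4.88 ± 0.18), CSRP1 (4.87 ± 0.19) and CCDC152 (4.43 ± 0.16), each with an edgeR adjusted p of at most 0.000182. The pluripotency list did not differ (3 of 17 lower and 1 higher, 4 adjusted over the list alone, camera adjusted p = 0.796). edgeR called 1052 genes higher and 1431 lower of 21092, and camera 11 of 28 lists, 0 with an estimated correlation. Mitochondrially encoded genes were lower as a list (0 of 13 called, 0 adjusted over the list alone, camera adjusted p = 0.0111, p = 0.815 with an estimated correlation). WT replicate 1 stood apart, with 10.21% of counts from these genes against 5.87% in replicate 2, and the WT pair had the largest spread of the 22 groups (chi-square per degree of freedom 53.29). The count rested on single libraries, with 744 and 689 genes without replicate 1 or 2 of the DKO-labelled cells and 7385 and 10304 without replicate 1 or 2 of the WT cells, and it was 4166 in a fit of all 44 libraries and 1153 with a transcript length offset.

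At day 9, the main comparison of the genotypes in vehicle cells, DKO-labelled cells had far lower levels of most sarcomere transcripts. TNNT2 was still present, at 36.5 and 31.6 CPM against 1390 and 1160 CPM in WT cells (scaled over all 44 libraries). The atrial myosin heavy chain MYH6 averaged 4020 ± 1300 CPM in WT and 0.0673 ± 0.045 CPM in DKO-labelled cells (-15.74 ± 1.15, edgeR adjusted p = 7.01e-07). Sarcomere and calcium-handling genes fell (23 of 24 lower, 24 adjusted over the list alone, camera adjusted p = 1.01e-25, p = 0.0789 with an estimated correlation), with a median change of -5.47, or -5.26 with genes at the counting floor set to their bounds. Examples are ACTC1 (-6.57 ± 0.22), MYL3 (-6.97 ± 0.24) and MYL7 (-5.87 ± 0.21). MYH7 had no counts in DKO-labelled vehicle libraries and was at least 1380-fold lower, against a floor of 3 counts over the group. Atrial genes fell (12 of 14 lower, 12 adjusted over the list alone, camera adjusted p = 1.04e-10, p = 0.0407 with an estimated correlation). NR2F1 and NR2F2, higher here, were left out of this list in genotype comparisons. The natriuretic peptide gene NPPA changed by -10.23 ± 0.33 and MYL4 by -8.38 ± 0.34. Cardiac progenitor genes fell (11 of 17 lower and 2 higher, 13 adjusted over the list alone, camera adjusted p = 1.74e-05, p = 0.0789 with an estimated correlation). NKX2-5 changed by -5.35 ± 0.26, TBX5 by -3.33 ± 0.18 and the pacemaker channel HCN4 by -4.29 ± 0.20. The ventricular list did not pass (6 of 12 lower and 3 higher, 9 adjusted over the list alone, camera adjusted p = 0.0521), although HEY2 fell (-4.83 ± 0.21).

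Endoderm genes, which code for secreted liver and gut proteins, were also lower in DKO-labelled vehicle cells at day 9 (14 of 17 lower, 14 adjusted over the list alone, camera adjusted p = 5.7e-12, p = 0.0407 with an estimated correlation). AFP changed by -9.95 ± 0.30, FGB by -8.73 [-10.43 to -7.58] and APOB by -5.23 ± 0.15. SERPINA1 had 2 counts in the DKO-labelled libraries, a ratio of 1940 with a 95% counting interval of 535 to 16000. Lymphatic endothelial genes fell (8 of 12 lower and 2 higher, 10 adjusted over the list alone, camera adjusted p = 0.00883, p = 0.12 with an estimated correlation), with PROX1, the regulator of lymphatic identity, at -2.87 ± 0.36 and NRP2 at -1.22 ± 0.11, while FLT4 rose (1.38 ± 0.18). Pan-endothelial genes fell (9 of 17 lower, 9 adjusted over the list alone, camera adjusted p = 0.00131, p = 0.148 with an estimated correlation), with ENG at -3.18 ± 0.21 and SOX17 at -3.31 ± 0.50, and so did the arterial and Notch list (8 of 16 lower and 1 higher, 9 adjusted over the list alone, camera adjusted p = 0.00131, p = 0.0956 with an estimated correlation), with JAG1 at -3.47 ± 0.22. Epicardial genes fell (7 of 11 lower, 7 adjusted over the list alone, camera adjusted p = 0.00129, p = 0.23 with an estimated correlation), with TBX18 at -3.20 ± 0.31, and so did smooth muscle genes (8 of 10 lower, 9 adjusted over the list alone, camera adjusted p = 1.04e-06, p = 0.0789 with an estimated correlation), with CNN1 at -2.46 ± 0.18. Hypoxia and glycolysis genes fell (18 of 20 lower, 18 adjusted over the list alone, camera adjusted p = 9.09e-13, p = 0.1 with an estimated correlation). PFKP changed by -3.20 ± 0.15 and HK2 by -2.53 ± 0.15. Nuclear oxidative phosphorylation genes fell (16 of 22 lower, 19 adjusted over the list alone, camera adjusted p = 1.04e-06, p = 0.29 with an estimated correlation). PPARGC1A, a regulator of mitochondrial genes, changed by -4.49 ± 0.33. Integrated stress response genes fell (14 of 23 lower, 16 adjusted over the list alone, camera adjusted p = 8.87e-05, p = 0.25 with an estimated correlation), with ATF3 at -2.48 ± 0.25, and p53 targets fell (8 of 17 lower and 1 higher, 9 adjusted over the list alone, camera adjusted p = 0.00268, p = 0.0789 with an estimated correlation), with CDKN1A at -2.33 ± 0.15.

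Other gene groups were higher in DKO-labelled vehicle cells at day 9. Cell cycle genes rose (16 of 20 higher, 18 adjusted over the list alone, camera adjusted p = 1.04e-06, p = 0.29 with an estimated correlation). MCM2 changed by 1.23 ± 0.17. Retinoic acid genes rose (9 of 18 higher and 4 lower, 13 adjusted over the list alone, camera adjusted p = 0.00602, p = 0.12 with an estimated correlation). The hindbrain Hox gene HOXB1 changed by 4.59 ± 0.20. Rises above the level minimum were largest in MAGEB3 (5.99 ± 0.36), HOXB9 (5.81 ± 0.19), ZNF558 (5.67 ± 0.24), the mesoderm factor LHX1 (4.86 ± 0.22), HOXB1 and CNTN1 (4.51 ± 0.21), with an edgeR adjusted p of at most 1.47e-07. CHCHD2 lay below that minimum, at 23.1 and 23.6 CPM against 0.0366 and 0 CPM in WT cells (scaled over all 44 libraries). ZNF558 was low in the WT libraries of days 7 and 9 only (0.437 to 1.28 CPM, against 23.5 to 51.5 CPM in all other libraries of either genotype). Cholesterol synthesis genes rose slightly (9 of 25 higher and 2 lower, 11 adjusted over the list alone, camera adjusted p = 0.0351, p = 0.29 with an estimated correlation). In the fibroblast and mesenchyme list members went both ways (4 of 14 higher and 3 lower, 8 adjusted over the list alone, camera adjusted p = 0.332, median -0.05, mean 0.34 and test upward). TWIST1 changed by 2.57 ± 0.12 and PDGFRB by -1.07 ± 0.16. Sphingolipid metabolism genes did not pass as a list (12 of 36 lower and 2 higher, 14 adjusted over the list alone, camera adjusted p = 0.0514), though S1PR1, a sphingosine 1-phosphate receptor, fell (-2.28 ± 0.15). Described COUP-TF targets, a list fixed beforehand from textbook knowledge, were lower (10 of 18 lower and 3 higher, 14 adjusted over the list alone, camera adjusted p = 0.00347, p = 0.102 with an estimated correlation). Lists without a call were pluripotency, mesendoderm, neural and neural crest, skeletal muscle, blood and fatty acid synthesis (camera adjusted p = 0.241, 0.395, 0.346, 0.337, 0.348 and 0.332). In the blood list the median was -0.11 while the mean and the test were positive. The unfolded protein response list was lower (9 of 20 lower, 10 adjusted over the list alone, camera adjusted p = 0.000938, p = 0.257 with an estimated correlation), as was the mitochondrially encoded list (5 of 13 lower, 5 adjusted over the list alone, camera adjusted p = 0.0278, p = 0.513 with an estimated correlation). edgeR called 3286 genes higher and 4585 lower of 22115, and camera 19 of 28 lists, 2 with an estimated correlation. Without replicate 2 of the DKO-labelled vehicle cells the count was 5019.

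The same genotype comparison was made at days 6 and 19 and in the inducible lines. Sarcomere genes were lower at day 6 (24 of 24 lower, 24 adjusted over the list alone, camera adjusted p = 5.43e-25, p = 0.299 with an estimated correlation), at day 19 (24 of 24 lower, 24 adjusted over the list alone, camera adjusted p = 3.02e-20, p = 0.129 with an estimated correlation) and in the inducible lines at day 9 (22 of 23 lower, 22 adjusted over the list alone, camera adjusted p = 3.32e-10, p = 0.312 with an estimated correlation). At day 6 MYBPC3 changed by -8.23 ± 0.18 and the cardiac factor GATA4 by -5.84 ± 0.14, whereas the pharyngeal mesoderm factor TBX1 rose by 9.04 [7.97 to 10.54]. At day 19 MYL2 changed by -10.96 ± 0.15 and IRX4, a ventricular factor, by -11.16 [-12.87 to -10.03]. Endoderm genes were lower at day 6 (14 of 15 lower, 14 adjusted over the list alone, camera adjusted p = 3.38e-07, p = 0.229 with an estimated correlation) and day 19 (15 of 16 lower, 15 adjusted over the list alone, camera adjusted p = 1.5e-07, p = 0.129 with an estimated correlation), where SERPINA1 was at least 26800-fold lower. Fibroblast and mesenchyme genes were higher at day 6 (10 of 14 higher and 2 lower, 12 adjusted over the list alone, camera adjusted p = 0.000123, p = 0.479 with an estimated correlation) and day 19 (14 of 14 higher, 14 adjusted over the list alone, camera adjusted p = 3.37e-10, p = 0.164 with an estimated correlation). The proteoglycan gene DCN changed by 8.42 ± 0.16 and OGN by 11.54 [10.37 to 13.22]. At day 19 skeletal muscle genes were higher (9 of 12 higher and 2 lower, 11 adjusted over the list alone, camera adjusted p = 0.00894, p = 0.286 with an estimated correlation). MYOG, a factor of skeletal muscle differentiation, changed by 6.04 ± 0.16. Cell cycle genes were higher at day 6 (19 of 20 higher, 20 adjusted over the list alone, camera adjusted p = 2.11e-14, p = 0.339 with an estimated correlation), day 19 (19 of 20 higher and 1 lower, 20 adjusted over the list alone, camera adjusted p = 5.41e-10, p = 0.156 with an estimated correlation) and in the inducible lines (20 of 20 higher, 20 adjusted over the list alone, camera adjusted p = 6.13e-16, p = 0.206 with an estimated correlation). Some lists went against day 9. Higher at day 6 were epicardial genes (6 of 10 higher and 3 lower, 9 adjusted over the list alone, camera adjusted p = 0.0422, p = 0.339 with an estimated correlation), integrated stress response genes (16 of 23 higher and 2 lower, 18 adjusted over the list alone, camera adjusted p = 0.00115, p = 0.618 with an estimated correlation) and unfolded protein response genes (12 of 20 higher and 2 lower, 15 adjusted over the list alone, camera adjusted p = 0.0424, p = 0.798 with an estimated correlation). Unfolded protein response genes were higher at day 19 too (18 of 20 higher and 1 lower, 19 adjusted over the list alone, camera adjusted p = 2.97e-05, p = 0.294 with an estimated correlation), where cholesterol synthesis genes were lower (15 of 25 lower and 4 higher, 19 adjusted over the list alone, camera adjusted p = 0.0218, p = 0.455 with an estimated correlation). Pan-endothelial genes (8 of 17 higher and 2 lower, 10 adjusted over the list alone, camera adjusted p = 0.0334, p = 0.539 with an estimated correlation) and p53 targets (11 of 17 higher and 2 lower, 13 adjusted over the list alone, camera adjusted p = 0.00983, p = 0.45 with an estimated correlation) were higher in the inducible lines. There pluripotency genes were higher as well (12 of 17 higher and 1 lower, 15 adjusted over the list alone, camera adjusted p = 3.17e-06, p = 0.206 with an estimated correlation), with L1TD1 at 2.81 ± 0.14. edgeR called 12137 of 25549 genes at day 6, 14897 of 24774 at day 19 and 9855 of 22608 in the inducible lines. In each, camera called 15 of 28 lists, 0 with an estimated correlation.

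**Figure D2:**
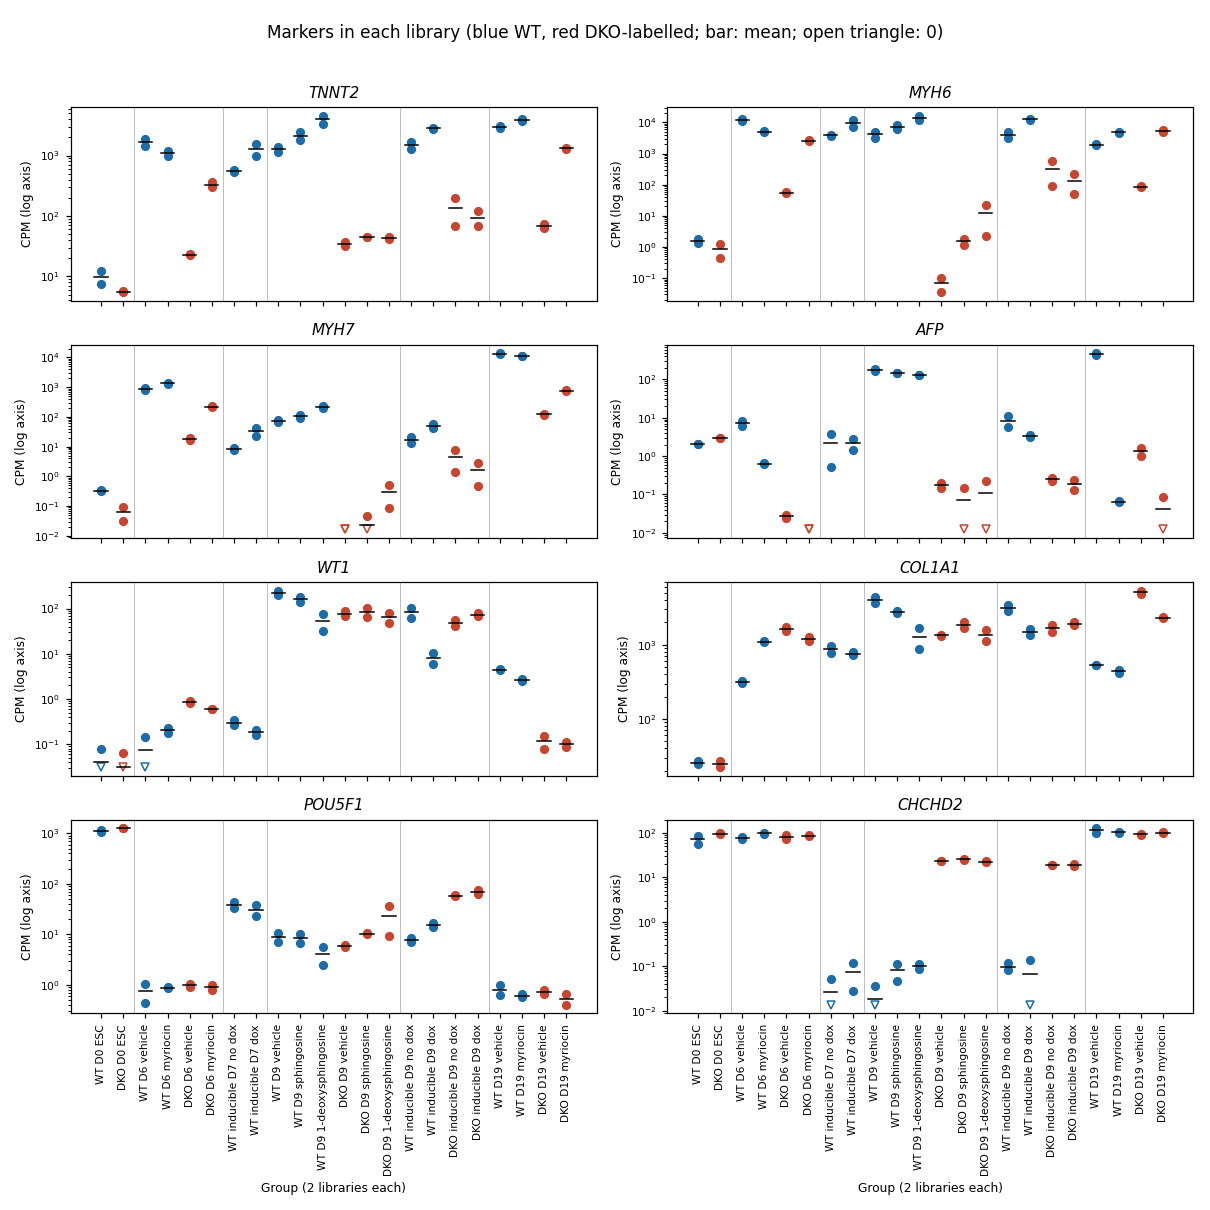
Level of 8 marker genes in CPM (log axis), 1 point per library, by group and day, with open triangles for libraries without reads. Scaled over all 44 libraries, MYH6 was at 4990 and 3210 CPM in WT and 0.101 and 0.036 CPM in DKO-labelled vehicle libraries of day 9, and AFP at 477 and 428 CPM with vehicle and 0.063 and 0.0658 CPM with myriocin in WT cells at day 19.

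Myriocin was tested for its effect on differentiation. In WT cells at day 6 it lowered endoderm and most sarcomere genes and raised mesenchymal, cell cycle and sterol genes. Sarcomere genes fell (16 of 24 lower and 3 higher, 20 adjusted over the list alone, camera adjusted p = 4.04e-06, p = 0.534 with an estimated correlation). RYR2, the calcium release channel, changed by -1.54 ± 0.10 and TNNI1 by -1.98 ± 0.14. The cardiac factor TBX5 fell (-4.26 ± 0.23) and TBX1 rose (4.76 [3.67 to 6.27]). Endoderm genes fell (11 of 15 lower, 11 adjusted over the list alone, camera adjusted p = 5.72e-06, p = 0.353 with an estimated correlation). TTR changed by -4.20 ± 0.17, SERPINA1 by -4.01 ± 0.32 and AFP by -3.52 ± 0.28. Fibroblast and mesenchyme genes rose (10 of 14 higher and 1 lower, 12 adjusted over the list alone, camera adjusted p = 9.24e-08, p = 0.534 with an estimated correlation). PDGFRB changed by 2.99 ± 0.12 and FBN1 by 2.44 ± 0.12. Cell cycle genes rose (20 of 20 higher, 20 adjusted over the list alone, camera adjusted p = 2.76e-18, p = 0.534 with an estimated correlation). Cholesterol synthesis genes rose (20 of 25 higher and 3 lower, 23 adjusted over the list alone, camera adjusted p = 4.89e-12, p = 0.534 with an estimated correlation), and unfolded protein response genes rose (18 of 20 higher, 19 adjusted over the list alone, camera adjusted p = 1.54e-09, p = 0.534 with an estimated correlation), with the chaperone gene HSP90B1 at 1.42 ± 0.13. In the sphingolipid list (17 of 35 higher and 6 lower, 24 adjusted over the list alone, camera adjusted p = 0.0259, p = 0.775 with an estimated correlation) the sphingomyelin synthase gene SGMS2 rose (3.10 ± 0.17) and UGCG rose (1.51 ± 0.12), while SGPP2 fell (-1.91 ± 0.10). The lymphatic list did not pass (camera adjusted p = 0.611). NR2F2 rose from 6.96 ± 0.43 to 25.9 ± 1.9 CPM (1.89 ± 0.12). Rises above the level minimum were largest in NRK (4.98 ± 0.14), COL5A3 (4.94 ± 0.23), EBF2 (4.80 ± 0.15), NEFM (4.55 ± 0.22), MMP19 (4.54 ± 0.19) and COL11A1 (4.43 ± 0.15). WNT2 fell (-4.27 ± 0.14). The edgeR adjusted p of these 7 genes was at most 1.75e-10. edgeR called 4140 genes higher and 3874 lower of 25549, and camera 14 of 28 lists, 0 with an estimated correlation.

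In DKO-labelled cells at day 6 myriocin went with higher cardiomyocyte transcripts. Sarcomere genes rose (23 of 24 higher, 24 adjusted over the list alone, camera adjusted p = 2.13e-63, p = 0.172 with an estimated correlation). MYH6 changed by 5.57 ± 0.15 and MYL3 by 5.42 ± 0.15. Cardiac progenitor genes rose (13 of 17 higher, 14 adjusted over the list alone, camera adjusted p = 7.18e-24, p = 0.172 with an estimated correlation). GATA4 changed by 3.72 ± 0.13. Above the level minimum, rises were largest in CSRP3 (5.88 ± 0.23), MYBPC3 (5.73 ± 0.17) and CKM (5.68 ± 0.18), and falls in NDST4 (-2.38 ± 0.28), PTCHD4 (-2.13 ± 0.22) and the kinetochore gene CENPE (-2.08 ± 0.12), with an edgeR adjusted p of at most 1.45e-05. The levels stayed below WT, as MYH6 reached 2670 ± 170 CPM against 12100 ± 1300 CPM in WT vehicle cells. The test of the difference between the genotypes (DKO-labelled minus WT) called 7121 genes and 14 of 28 lists, 0 with an estimated correlation. It was positive for sarcomere genes (23 of 24 higher, 23 adjusted over the list alone, camera adjusted p = 3.5e-30, p = 0.33 with an estimated correlation) and negative for cell cycle genes (20 of 20 lower, 20 adjusted over the list alone, camera adjusted p = 1.67e-18, p = 0.412 with an estimated correlation) and cholesterol synthesis genes (20 of 25 lower and 4 higher, 25 adjusted over the list alone, camera adjusted p = 5.74e-09, p = 0.501 with an estimated correlation). NR2F2 rose with myriocin in WT cells and fell in DKO-labelled cells (-0.79 ± 0.11), a difference of -2.69 ± 0.16 (edgeR adjusted p = 1.87e-09). edgeR called 1533 genes higher and 1014 lower with myriocin in DKO-labelled cells, and camera 13 of 28 lists, 0 with an estimated correlation. The count was 1395 and 1648 without replicate 1 or 3 of the DKO-labelled myriocin cells.

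At day 19 myriocin lowered endoderm and glycolysis genes in WT cells. Endoderm genes fell (15 of 16 lower, 15 adjusted over the list alone, camera adjusted p = 4.14e-23, p = 0.0225 with an estimated correlation), with AFP from 447 ± 31 CPM to 4 counts over both libraries (-12.71 [-14.67 to -11.44]), ALB at -6.67 [-7.32 to -6.12] and APOB at -8.03 [-8.95 to -7.27]. SERPINA1 had no counts with myriocin and was at least 20000-fold lower. The plasma protein genes C3 (-6.27 ± 0.14) and ITIH2 (-7.04 [-7.76 to -6.46]) fell as well. Sarcomere genes went both ways (8 of 24 lower and 6 higher, 15 adjusted over the list alone, camera adjusted p = 0.353). Hypoxia and glycolysis genes fell (15 of 20 lower, 18 adjusted over the list alone, camera adjusted p = 1.15e-14, p = 0.22 with an estimated correlation). Mitochondrially encoded genes rose (8 of 13 higher, 11 adjusted over the list alone, camera adjusted p = 9.1e-06, p = 0.491 with an estimated correlation). Rises above the level minimum were largest in OSR1 (3.61 ± 0.12), P2RX1 (3.55 ± 0.21), the TEK ligand gene ANGPT1 (3.19 ± 0.09), DSCAM (2.71 ± 0.19), THSD7B (2.51 ± 0.18) and COL14A1 (2.38 ± 0.08), with an edgeR adjusted p of at most 9.87e-07. The lymphatic list did not pass (camera adjusted p = 0.936). NR2F1 and NR2F2 did not change past the threshold (-0.31 ± 0.34 and -0.09 ± 0.15). edgeR called 1852 genes higher and 2322 lower of 24774, and camera 11 of 28 lists, 1 with an estimated correlation. The count was 1968 and 2231 without replicate 1 or 3 of the WT myriocin cells, 1995 in a fit of all 44 libraries and 2217 with a transcript length offset.

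In DKO-labelled cells at day 19 myriocin again went with higher cardiomyocyte transcripts. Sarcomere genes rose (24 of 24 higher, 24 adjusted over the list alone, camera adjusted p = 1.28e-26, p = 0.129 with an estimated correlation), with MYH6 from 83.4 ± 3.5 to 5190 ± 540 CPM (5.96 ± 0.10) and PLN at 5.07 ± 0.08. Per library MYH6 passed the level of WT vehicle cells (4810 and 5560 against 1890 and 2010 CPM, scaled over all 44 libraries), while MYH7 stayed below (745 and 792 against 13200 and 13700 CPM). Pan-endothelial genes rose (12 of 17 higher and 1 lower, 13 adjusted over the list alone, camera adjusted p = 4.13e-05, p = 0.129 with an estimated correlation). KDR changed by 2.49 ± 0.08. Fibroblast and mesenchyme genes fell (10 of 14 lower, 10 adjusted over the list alone, camera adjusted p = 2.07e-05, p = 0.284 with an estimated correlation). DCN changed by -3.94 ± 0.11. Above the level minimum, rises were largest in BRINP3 (8.92 [8.17 to 9.86]), TECRL (7.34 ± 0.13) and the myoglobin gene MB (7.15 [6.72 to 7.64]), and falls in PADI2 (-6.14 [-6.74 to -5.65]), SPARCL1 (-4.89 ± 0.12) and EGFL6 (-4.45 ± 0.13), with an edgeR adjusted p of at most 1.04e-11. The test of the difference from WT was positive for sarcomere genes (24 of 24 higher, 24 adjusted over the list alone, camera adjusted p = 2.15e-29, p = 0.0661 with an estimated correlation) and endoderm genes (14 of 16 higher, 14 adjusted over the list alone, camera adjusted p = 7.28e-12, p = 0.0661 with an estimated correlation). Of the endoderm members 7 of 16 were at the counting floor in some group, and members near absent in DKO-labelled vehicle cells had no room to fall. edgeR called 11378 genes in DKO-labelled cells and 8913 for the difference, and camera 12 of 28 lists, 0 with an estimated correlation, and 11 of 28 lists, 0 with an estimated correlation.

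1-deoxysphingosine was compared with vehicle in WT cells at day 9. Every sarcomere gene tested was higher and epicardial, fibroblast and stress-response genes were lower. Sarcomere genes rose (24 of 24 higher, 24 adjusted over the list alone, camera adjusted p = 8.76e-23, p = 0.15 with an estimated correlation). TNNC1 changed by 1.94 ± 0.17, MYL3 by 1.95 ± 0.17 and MYOM1 by 1.97 ± 0.19. Ventricular genes rose (8 of 12 higher and 2 lower, 10 adjusted over the list alone, camera adjusted p = 2e-04, p = 0.0809 with an estimated correlation). NPPB changed by 2.22 ± 0.17 and IRX5 by 1.26 ± 0.14. Cholesterol synthesis genes rose (19 of 25 higher, 22 adjusted over the list alone, camera adjusted p = 3.93e-16, p = 0.0515 with an estimated correlation). HMGCS1 changed by 0.88 ± 0.09. Nuclear oxidative phosphorylation genes rose (21 of 22 higher, 22 adjusted over the list alone, camera adjusted p = 1.96e-13, p = 0.203 with an estimated correlation), as did mitochondrially encoded genes (12 of 13 higher, 13 adjusted over the list alone, camera adjusted p = 9.2e-09, p = 0.203 with an estimated correlation). CKMT2 changed by 1.35 ± 0.22 and MT-ND2 by 0.80 ± 0.14. Epicardial genes fell (5 of 11 lower, 5 adjusted over the list alone, camera adjusted p = 7.53e-06, p = 0.203 with an estimated correlation). TBX18 changed by -2.22 ± 0.29 and BNC1 by -3.11 ± 0.43. Fibroblast and mesenchyme genes fell (9 of 14 lower, 13 adjusted over the list alone, camera adjusted p = 1.03e-07, p = 0.203 with an estimated correlation). DCN changed by -2.68 ± 0.41 and COL1A1 by -1.65 ± 0.25. Integrated stress response genes fell (15 of 23 lower and 1 higher, 18 adjusted over the list alone, camera adjusted p = 2.82e-09, p = 0.203 with an estimated correlation). The amino acid synthesis gene ASNS changed by -1.70 ± 0.18 and PHGDH by -1.94 ± 0.25. The lymphatic list did not pass (4 of 12 lower and 1 higher, 5 adjusted over the list alone, camera adjusted p = 0.158, median 0.02, mean -0.31 and test downward), and its members MAF (-1.44 ± 0.14), PDPN (-1.09 ± 0.17) and RELN (-1.5 ± 0.25) fell. Sphingolipid genes did not move as a list (5 of 36 higher and 3 lower, 9 adjusted over the list alone, camera adjusted p = 0.753), although SMPD3 fell (-2.69 ± 0.35). Rises above the level minimum were largest in PPP1R3A (2.59 ± 0.33), C7 (2.32 ± 0.25), KCNQ3 (2.22 ± 0.30), NPPB, ADCY5 (2.14 ± 0.27) and ACTA1 (2.11 ± 0.16). Falls above it were largest in ANXA8L1 (-5.70 ± 0.45), UPK3B (-5.63 ± 0.67), PRPH (-5.23 ± 0.42), COL8A2 (-4.93 ± 0.51), ANXA8 (-4.65 ± 0.41) and CHI3L1 (-4.33 ± 0.38). ANXA8 and ANXA8L1 are near-identical copies, so how reads were split between them is uncertain. The edgeR adjusted p of these 12 genes was at most 0.00103. NR2F1, NR2F2 and SPTLC1 stood at -0.99 ± 0.24, -0.78 ± 0.17 and -0.37 ± 0.11 (edgeR adjusted p = 0.0147, 0.00862 and 0.0336). These 3 calls were lost without replicate 2 of the 1-deoxysphingosine cells, those of NR2F1 and SPTLC1 also without replicate 1 of the vehicle cells, and that of SPTLC1 without the low count filter and with a transcript length offset. edgeR called 1653 genes higher and 1878 lower of 22115, and camera 17 of 28 lists, 0 with an estimated correlation. The count was 1295 without replicate 2 of the 1-deoxysphingosine cells and 2340 without replicate 2 of the vehicle cells, and 5315 in a fit of all 44 libraries.

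Sphingosine, which carries the carbon 1 hydroxyl, gave far fewer calls against the same WT vehicle libraries. edgeR called 12 genes, of which 1 was higher, while 2643 had an unadjusted p under 0.05 and DESeq2 called 409. The genes that fell included the retinoic acid binding protein gene CRABP1 (-3.25 ± 0.38), the neural crest factor PAX3 (-2.30 ± 0.32), WNT3A (-4.60 ± 0.53), MMRN1 (-3.15 ± 0.35), the axon guidance gene SLIT1 (-2.08 ± 0.31) and NKAIN3-IT1 (-1.63 ± 0.24), and SOX1 had 1 count with sphingosine, a ratio of 179 with a 95% counting interval of 31.8 to 7120. CFC1, a NODAL co-receptor with a near-identical copy, rose (0.89 ± 0.13, edgeR adjusted p = 0.0445). Neural and neural crest genes fell as a list (1 of 15 lower, 8 adjusted over the list alone, camera adjusted p = 4.2e-08, p = 0.155 with an estimated correlation), and sarcomere genes rose as a list (0 of 24 called, 21 adjusted over the list alone, camera adjusted p = 2.67e-18, p = 0.155 with an estimated correlation). Camera called 11 of 28 lists, 0 with an estimated correlation. NR2F1 and NR2F2 did not change past the threshold (-1.25 ± 0.24 and -0.25 ± 0.17). The calls rested on single libraries. The count was 2 and 0 without replicate 1 or 2 of the sphingosine cells, where every gene named here lost its call, and 868 without replicate 1 of the vehicle cells. Of the genes called, 8.3% were higher, against 51.1% of 716 in a fit of all 44 libraries, 44.5% of 1262 without the low count filter and 52.6% with DESeq2.

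The compounds, which differ by the carbon 1 hydroxyl, were compared directly in WT cells at day 9. Sarcomere genes were higher with 1-deoxysphingosine than with sphingosine (12 of 24 higher, 22 adjusted over the list alone, camera adjusted p = 7.1e-18, p = 0.152 with an estimated correlation). TNNC1 changed by 1.15 ± 0.16. Cholesterol genes were higher (15 of 25 higher, 23 adjusted over the list alone, camera adjusted p = 9.52e-26, p = 0.0142 with an estimated correlation), with INSIG1 at 0.90 ± 0.10, and so were ventricular genes (5 of 12 higher, 10 adjusted over the list alone, camera adjusted p = 4.31e-05, p = 0.0417 with an estimated correlation), with NPPB at 2.15 ± 0.17, and fatty acid synthesis genes (3 of 12 higher, 7 adjusted over the list alone, camera adjusted p = 8.64e-07, p = 0.0417 with an estimated correlation). Epicardial genes were lower (5 of 11 lower, 7 adjusted over the list alone, camera adjusted p = 4.18e-09, p = 0.135 with an estimated correlation), with TBX18 at -2.50 ± 0.30, and so were integrated stress response genes (8 of 23 lower, 15 adjusted over the list alone, camera adjusted p = 7.07e-10, p = 0.189 with an estimated correlation). ANXA8L1 (-4.03 ± 0.46) and PRPH (-3.81 ± 0.45) were lower as well. The edgeR adjusted p of the 6 genes named in this comparison was at most 0.00366. The compounds did not differ past the threshold in NR2F1 (difference 0.27 ± 0.25, 95% interval -0.27 to 0.80) or NR2F2 (-0.53 ± 0.17, -0.91 to -0.16). edgeR called 765 genes, 289 higher with 1-deoxysphingosine, and camera 13 of 28 lists, 3 with an estimated correlation. The count was 66 and 491 without replicate 2 or 1 of the sphingosine cells, 137 and 1659 without replicate 2 or 1 of the 1-deoxysphingosine cells, 2045 in a fit of all 44 libraries, 1993 without the low count filter and 1212 with DESeq2. TNNC1 lost its call without replicate 2 of the sphingosine cells.

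The same lipids were given to DKO-labelled cells. 1-deoxysphingosine called 64 genes, 53 of them higher, with EGR2 at 2.68 ± 0.39, the Wnt antagonist DKK1 at 2.24 ± 0.35, the imprinted gene DLK1 at -1.5 ± 0.20 and FOXP2 at -1.51 ± 0.23 (edgeR adjusted p at most 0.0261). MYH6 stood at 22.2 and 2.30 CPM in the 2 libraries against 0.101 and 0.0360 CPM with vehicle. The sarcomere list was higher (1 of 24 higher, 4 adjusted over the list alone, camera adjusted p = 0.00118, p = 0.546 with an estimated correlation), with a median change of 0.15. Pluripotency genes were higher as a list (0 of 17 called, 4 adjusted over the list alone, camera adjusted p = 0.000182, p = 0.436 with an estimated correlation), with replicate 1 apart (POU5F1 at 37 and 9.13 CPM, against 6.26 and 5.51 CPM with vehicle). The number of genes called was 0 and 0 without replicate 1 or 2 of the vehicle cells, 5 and 174 without replicate 1 or 2 of the 1-deoxysphingosine cells, 843 in a fit of all 44 libraries (63.7% higher, against 82.8%), 899 without the low count filter (60.4% higher) and 338 with DESeq2, and all genes named here lost their calls without either vehicle library. For sphingosine edgeR called 0 genes, with 1227 at an unadjusted p under 0.05 and 29 by DESeq2. The direct comparison of the compounds in DKO-labelled cells called 60 genes, with CXCR4 higher (2.16 ± 0.28) and KRT7 lower (-2.14 ± 0.25) with 1-deoxysphingosine (edgeR adjusted p at most 0.0195) and integrated stress response genes lower (1 of 23 lower, 16 adjusted over the list alone, camera adjusted p = 2.03e-10, p = 0.206 with an estimated correlation). That count was 0 without 1-deoxysphingosine replicate 1, 130 without its replicate 2, 2 without sphingosine replicate 1 and 0 without its replicate 2, and both genes lost their calls without 1-deoxysphingosine replicate 1. NR2F1 and NR2F2 did not differ past the threshold between the compounds (-0.22 ± 0.22, 95% interval -0.70 to 0.27, and -0.19 ± 0.17, -0.55 to 0.17).

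The difference between the genotypes in the response to 1-deoxysphingosine was tested itself. It was negative for sarcomere genes (14 of 24 lower, 17 adjusted over the list alone, camera adjusted p = 1.31e-13, p = 0.304 with an estimated correlation), with MYL7 at -1.79 ± 0.24 and TNNC1 at -1.79 ± 0.27, and for cholesterol synthesis genes (10 of 25 lower, 15 adjusted over the list alone, camera adjusted p = 1.07e-11, p = 0.116 with an estimated correlation), with INSIG1 at -1.14 ± 0.14. It was positive for pluripotency genes (7 of 17 higher, 13 adjusted over the list alone, camera adjusted p = 7.16e-06, p = 0.308 with an estimated correlation), fibroblast and mesenchyme genes (5 of 14 higher, 12 adjusted over the list alone, camera adjusted p = 8.77e-07, p = 0.308 with an estimated correlation), epicardial genes (4 of 11 higher, 8 adjusted over the list alone, camera adjusted p = 3.14e-05, p = 0.308 with an estimated correlation) and lymphatic endothelial genes (4 of 12 higher, 5 adjusted over the list alone, camera adjusted p = 0.00284, p = 0.304 with an estimated correlation). Among single genes, ANXA8L1 differed by 5.39 ± 0.60 and COL8A2 by 4.90 ± 0.68. The edgeR adjusted p of these 5 genes was at most 0.00585. NR2F1 and NR2F2 did not differ in their response (-0.03 ± 0.33, 95% interval -0.74 to 0.68, and 0.05 ± 0.24, -0.47 to 0.57). edgeR called 1354 genes and camera 15 of 28 lists, 0 with an estimated correlation for this difference, and edgeR 1 gene for sphingosine, MOXD1 (-2.01 ± 0.22). Leaving out 1 library moved the first count to between 240 (DKO-labelled vehicle replicate 2) and 3000 (WT vehicle replicate 1), with 374 without DKO-labelled vehicle replicate 1, 589 without WT vehicle replicate 2, 549 and 692 without DKO-labelled 1-deoxysphingosine replicate 1 or 2, and 2831 and 430 without WT 1-deoxysphingosine replicate 1 or 2, and it was 3287 in a fit of all 44 libraries and 2776 without the low count filter. The second was 615 without WT vehicle replicate 1, 3 and 2 without WT sphingosine replicate 1 or 2, and 0 without WT vehicle replicate 2, DKO-labelled vehicle replicate 2 or either DKO-labelled sphingosine library, with DESeq2 at 139. MOXD1 lost its call without replicate 2 of either vehicle group and without either DKO-labelled sphingosine library.

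**Figure D3:**
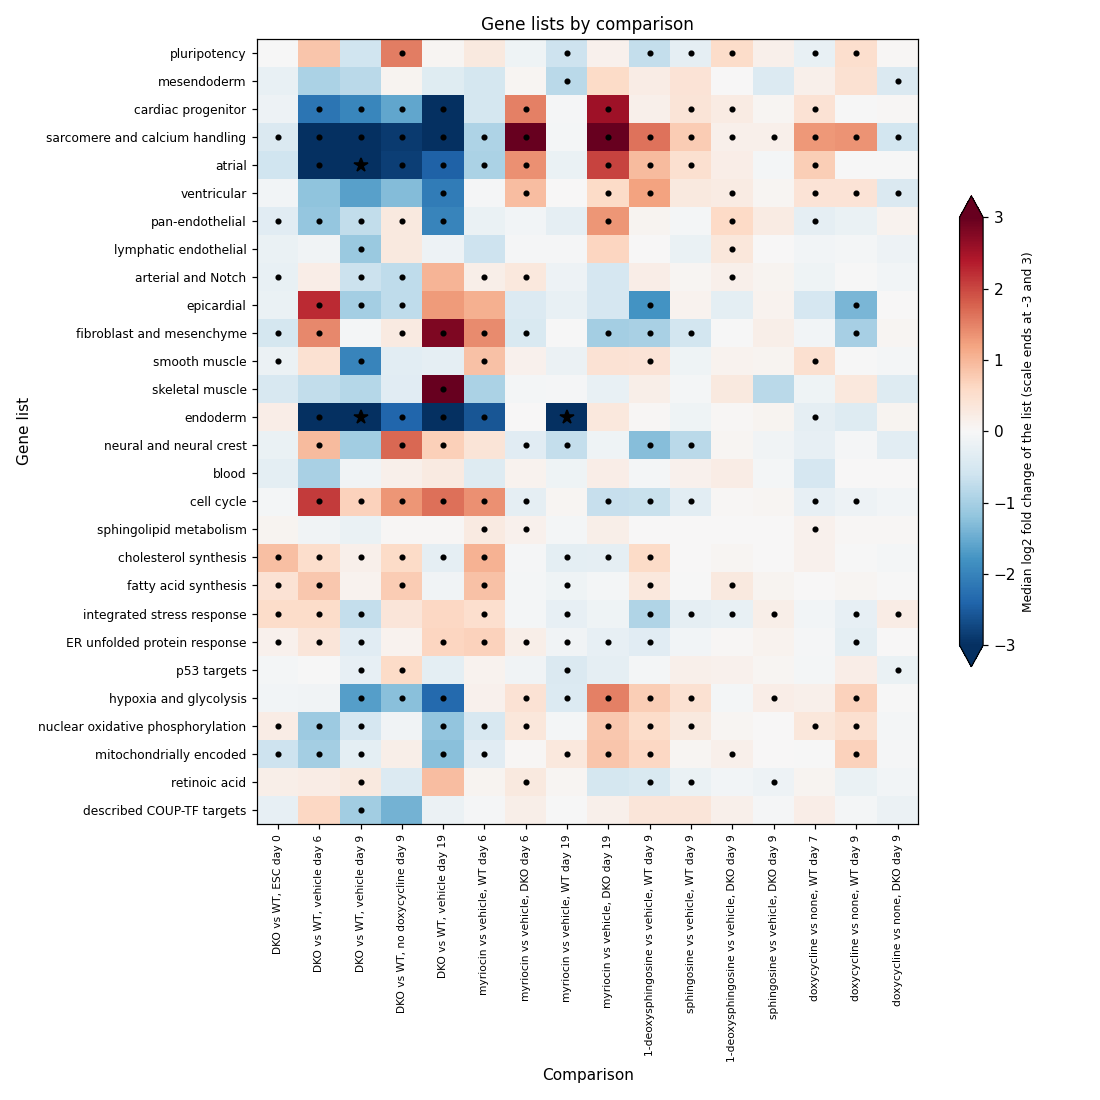
Median log2 fold change of the 28 gene lists in 16 comparisons (colour scale ending at -3 and 3), with a dot where camera's adjusted p was under 0.05 with the preset correlation only and a star where it also was with an estimated correlation. The sarcomere list has a median of -5.47 for DKO-labelled against WT vehicle cells at day 9, 1.63 for 1-deoxysphingosine and 0.75 for sphingosine in WT cells.

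SPTLC1 C133W was induced with doxycycline. No group separates the drug, SPTLC1 excess and C133W. WT cells at day 9 come first. Epicardial genes fell (6 of 11 lower, 6 adjusted over the list alone, camera adjusted p = 2.46e-06, p = 0.195 with an estimated correlation), with TBX18 from 244 ± 98 to 15.1 ± 5.8 CPM (-4.00 ± 0.34), WT1 at -3.32 ± 0.27 and TCF21 at -2.76 ± 0.24. Fibroblast and mesenchyme genes fell (10 of 14 lower, 12 adjusted over the list alone, camera adjusted p = 6.32e-10, p = 0.235 with an estimated correlation). DDR2 changed by -1.72 ± 0.15 and COL1A1 by -1.05 ± 0.13. Mitochondrially encoded genes rose (13 of 13 higher, 13 adjusted over the list alone, camera adjusted p = 6.78e-17, p = 0.195 with an estimated correlation), with MT-CO2 at 0.81 ± 0.06, as did nuclear oxidative phosphorylation genes (18 of 22 higher, 21 adjusted over the list alone, camera adjusted p = 1.17e-13, p = 0.289 with an estimated correlation), with UQCRC2 at 0.64 ± 0.09. Sarcomere genes rose (13 of 23 higher, 21 adjusted over the list alone, camera adjusted p = 5.94e-09, p = 0.551 with an estimated correlation). TNNI3 changed by 1.13 ± 0.18. Unfolded protein response genes fell (11 of 20 lower, 15 adjusted over the list alone, camera adjusted p = 1.19e-07, p = 0.235 with an estimated correlation). CALR changed by -0.62 ± 0.08 and HSPA5 by -0.49 ± 0.06. The sphingolipid list (6 of 36 higher and 2 lower, 8 adjusted over the list alone, camera adjusted p = 0.396) and the lymphatic list (2 of 11 lower and 1 higher, 3 adjusted over the list alone, camera adjusted p = 0.914, median -0.05, mean 0.04 and test downward) did not pass. NR2F1 fell from 69.4 ± 9.6 to 20.9 ± 2 CPM (-1.73 ± 0.27) and NR2F2 from 136 ± 20 to 45.1 ± 5.8 CPM (-1.59 ± 0.15). Above the level minimum, the genes of largest rise included KCNQ3 (2.97 ± 0.37), ICAM5 (2.50 ± 0.28), RRAD (2.37 ± 0.38), FHL2 (2.32 ± 0.25) and TRIM9 (2.29 ± 0.28), and those of largest fall, besides TBX18, ARSI (-3.74 ± 0.35), SGCD (-3.74 ± 0.36), NPHS1 (-3.43 ± 0.36), AQP3 (-3.36 ± 0.29) and TMEM151A (-3.34 ± 0.58), with an edgeR adjusted p of at most 0.00301. edgeR called 1667 genes higher and 1912 lower of 22608, and camera 11 of 28 lists, 0 with an estimated correlation. The count was 969 without replicate 2 of the untreated cells (33.2% higher, against 46.6%) and 951 without replicate 2 of the doxycycline cells (34.9% higher).

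In WT cells at day 7 doxycycline raised cardiac genes. Above the level minimum and besides SPTLC1, NPPA (3.38 ± 0.58) and KCNH7 (3.18 ± 0.45) had the largest rises, and the erythroid heme synthesis gene ALAS2 (-2.03 ± 0.26), S100A14 (-1.85 ± 0.28) and ITLN2 (-1.60 ± 0.26) the largest falls (edgeR adjusted p at most 0.00911). Sarcomere genes rose (12 of 23 higher, 20 adjusted over the list alone, camera adjusted p = 8.32e-11, p = 0.455 with an estimated correlation). RYR2 changed by 2.14 ± 0.24. NR2F1 and NR2F2 did not change past the threshold (0.35 ± 0.33 and -0.17 ± 0.15). edgeR called 1080 genes higher and 496 lower, and camera 11 of 28 lists, 0 with an estimated correlation. Without replicate 1 of the untreated cells 8 genes remained past the threshold and all genes named here except SPTLC1 lost their calls, without replicate 1 of the doxycycline cells the count was 106 (86.8% higher, against 68.5%), and it was 2706 without the low count filter and 849 with a transcript length offset.

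In DKO-labelled cells at day 9 doxycycline called 1 gene, SPTLC1 itself, from 59.1 ± 0.95 to 127 ± 12 CPM. By edgeR 1257 genes had an unadjusted p under 0.05, DESeq2 called 35 genes (40% higher) and 424 were called without the low count filter (28.8% higher). The integrated stress response list was higher (0 of 23 called, 0 adjusted over the list alone, camera adjusted p = 7.78e-10, p = 0.242 with an estimated correlation) and the p53 list lower (0 of 17 called, 1 adjusted over the list alone, camera adjusted p = 1.76e-06, p = 0.242 with an estimated correlation). The test of the difference between the genotypes called 1295 genes and 12 of 28 lists, 0 with an estimated correlation. SPTLC1 induction itself did not differ (0.04 ± 0.17, 95% interval -0.32 to 0.41). The difference was positive for epicardial genes (6 of 11 higher, 6 adjusted over the list alone, camera adjusted p = 4.52e-06, p = 0.174 with an estimated correlation), with TBX18 at 4.94 ± 0.46 and WT1 at 3.90 ± 0.35, and for fibroblast and mesenchyme genes (7 of 14 higher, 10 adjusted over the list alone, camera adjusted p = 1.37e-09, p = 0.222 with an estimated correlation), with DDR2 at 2.04 ± 0.20. It was negative for mitochondrially encoded genes (13 of 13 lower, 13 adjusted over the list alone, camera adjusted p = 9.8e-17, p = 0.174 with an estimated correlation), with MT-CO2 at -0.79 ± 0.09, and for sarcomere genes (4 of 23 lower, 20 adjusted over the list alone, camera adjusted p = 1.39e-10, p = 0.392 with an estimated correlation). NR2F2 differed by 1.72 ± 0.20 (edgeR adjusted p = 0.00188). SPTLC1 in DKO-labelled cells lost its call without replicate 1 or 2 of the untreated cells or replicate 2 of the doxycycline cells and in a fit of the day 9 libraries alone, an alternative chosen after seeing the data. The count for the difference was 279, 387, 513, 516 and 708 without WT doxycycline replicate 2, WT untreated replicate 2, DKO-labelled untreated replicate 2 and DKO-labelled doxycycline replicate 1 or 2 (63.4% to 73.8% higher, against 59%), 2564 without the low count filter and 768 with a transcript length offset.

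**Figure D4:**
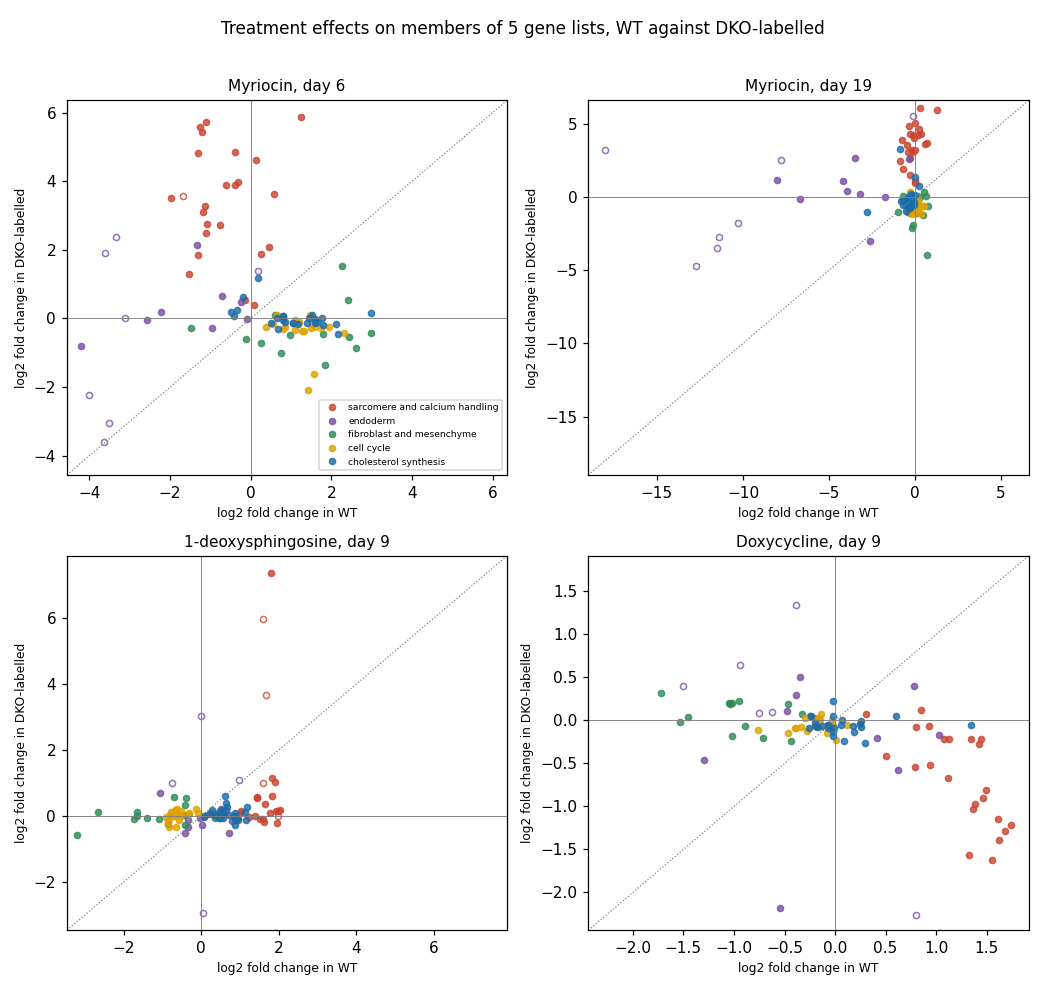
Log2 fold change in WT (horizontal) and DKO-labelled cells (vertical) of the members of 5 gene lists under myriocin at days 6 and 19, 1-deoxysphingosine and doxycycline, 1 point per gene, open where a whole group had 3 counts or fewer. Under myriocin at day 19 sarcomere genes have a median of -0.07 in WT and 3.67 in DKO-labelled cells, and under doxycycline the fibroblast gene DDR2 changed by -1.72 in WT cells.

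Responses of WT cells were then compared across experiments that share no control libraries. Across 21453 genes the response to 1-deoxysphingosine correlated with that to doxycycline at day 9 with Pearson's r of 0.24 and Spearman's rho of 0.37, or an r of 0.64 over the 11085 genes with more reads. Genes called higher in both numbered 799, against 126.1 if the calls were independent, genes called lower in both 719 against 164.1, and genes called in opposite directions 67 against 287.7. With doxycycline at day 7 the r was 0.20 (0.54 over genes with more reads). Between 1-deoxysphingosine and myriocin at day 6 it was -0.23 (-0.36), with 1627 genes called in opposite directions against 623.6. Myriocin at day 6 and myriocin at day 19 gave an r of -0.03 (-0.03), and 1-deoxysphingosine and myriocin at day 19 an r of 0.02 (0.05). Doxycycline at day 9 and doxycycline at day 7 gave an r of 0.04 over all genes (0.36 over genes with more reads). Of the genes called in both, 396 were higher in both against 79.6, and 84 went in opposite directions against 127.9. Of the 10 pairs computed, those of doxycycline with myriocin are left out here. The correlations are across genes, which are not independent replicates, so no p is given.

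Genes that differed between DKO-labelled and WT cells were followed as sets in the treatments of other experiments. The 3195 genes higher in DKO-labelled vehicle cells at day 9 had a median change of -0.13 with doxycycline in WT cells at day 9 and -0.01 in DKO-labelled cells, and the 4512 genes lower had 0.10 and 0.00. With 1-deoxysphingosine in WT cells, the 4936 genes higher in the DKO-labelled inducible lines had a median of -0.14 and the 4740 lower 0.16, against 0.07 and -0.03 in DKO-labelled cells. Camera called 27 of the 32 tests of these sets with the preset correlation and 0 with an estimated correlation. The sets were chosen on libraries whose NR2F1 and NR2F2 transcripts did not follow the label.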

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

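The tests of a difference between the genotypes were planned, and the tests of explanations in the last 2 paragraphs of this part were chosen after the results were seen.

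Responses to treatment that differed between WT and DKO-labelled cells by a test of the difference itself are given here (log2, DKO-labelled minus WT, edgeR adjusted p under the threshold of 0.05). For myriocin at day 6 the test called 7121 genes. NR2F1 differed by -3.04, NR2F2 by -2.69 and SPTLC1 by -0.61. WNT2, a signal of early heart mesoderm (10.39), and the muscle creatine kinase gene CKM (8.31) had positive differences, and NRK (-6.18) and COL5A3 (-6.14) negative ones. EDN3 (edgeR adjusted p = 1.74e-08) and the readthrough gene HSPB2-C11orf52 (edgeR adjusted p = 1.61e-10) differed as well, but a group near 0 counts allows no fold. For myriocin at day 19 the test called 8913 genes, with NR2F2 at -1.61, SPTLC1 at -0.34, IRX4 at 8.86, SERPIND1 at 8.73, C3 at 7.40, PADI2 at -6.43, DCN at -4.65 and SPX at -4.39. For 1-deoxysphingosine it called 1354 genes, with ANXA8L1 at 5.39, PAX6 at 4.90, COL8A2 at 4.90, SPHKAP at -3.16 and PAPPA2 at -2.67. That count rested on single libraries. For sphingosine it called 1 gene, MOXD1 (-2.01), a call that rested on single libraries as given above, and 139 with DESeq2. For doxycycline it called 1295 genes, with NR2F2 at 1.72, TBX18 at 4.94, WT1 at 3.90, AQP3 at 3.84, TRIM9 at -3.17, IRX4 at -3.06 and KCNQ3 at -3. That count and the calls of IRX4 and KCNQ3 rested on single libraries.

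NR2F1 and NR2F2 transcripts were higher in DKO-labelled than in WT vehicle cells at days 6, 9 and 19. A smaller share of cardiomyocytes with other cell types raised alike is argued against by the endoderm list, with a median of -4.38 at day 9. An exchange of single libraries between the labels is argued against by NLRP2, ZNF615 and ZNF93, named for the undifferentiated cells, for which the lowest of all WT libraries was at least 4.75 times the highest DKO-labelled library. An exchange of the labels as a whole stays open, since it and an edited locus that is still transcribed both give NR2F1 higher in DKO-labelled cells (2.59 at day 9), although in undifferentiated cells, near the detection limit, both genes were lower there (NR2F1 at 3 against 27 counts, NR2F2 at 0.206 against 0.897 CPM). An intact locus would give 3998 reads of NR2F1-205 in DKO-labelled libraries at the WT share, and an edited one few or none. None were seen, but this form was picked for that, so it decides nothing. Loss of feedback of the proteins on their own genes and a change in the cells that express them were not tested and stay open.

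Doxycycline called 3579 genes in WT cells and 1 in DKO-labelled cells at day 9, where edgeR gave 1257 genes an unadjusted p under 0.05 and DESeq2 called 35. Lower precision in DKO-labelled cells as the whole cause is argued against by the 1295 genes called in the test of the difference. Weaker induction at day 9 is argued against by the difference of 0.04 in the SPTLC1 response. Weaker induction earlier stays open, as no DKO-labelled cells were collected at day 7. WT doxycycline cells then had 439 CPM of SPTLC1 and 102 CPM at day 9 (scaled over all 44 libraries). A single WT library is argued against by a count of 951 with WT doxycycline replicate 2 left out (969 with WT untreated replicate 2), the lowest for the WT libraries. A need for NR2F1 and NR2F2 may explain the difference, but the DKO-labelled cells also differed from WT cells in 9855 genes before doxycycline. The epicardial gene WT1 was not absent there, at 48.7 CPM against 82.8 CPM in WT cells, with factors over all 44 libraries. Genotype is confounded with cell state and perhaps WT stock (below), so all stay open.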

How the results depend on the processing

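All alternatives but those named as chosen later were set before the data were seen. Across alternatives 10332 values of named genes kept their direction and side of the threshold, 583 lost the call, 22 gained it and 0 turned direction. Lost calls numbered 46 of 937 in a fit of all 44 libraries, 61 with a transcript length offset, 17 with the replicate block, 5 with RLE factors, 2 without the low count filter and 4 of 928 with DESeq2. Counts within 1.5 times of the reported ones are not listed. In a fit of all 44 libraries the counts were 4166 for undifferentiated cells, 1995 for myriocin in WT cells at day 19, 5315, 716 and 2045 in WT cells for 1-deoxysphingosine, sphingosine and the first against the second, 843, 42 and 542 for the same in DKO-labelled cells, 3287 and 285 for the genotype differences of these lipids, and 4 for doxycycline in DKO-labelled cells. Without the low count filter they were 1262 (sphingosine) and 1993 (1-deoxysphingosine against sphingosine) in WT cells, 899, 368 and 837 in DKO-labelled cells for 1-deoxysphingosine, sphingosine and their comparison, and 2776 and 898 for the genotype differences. For doxycycline they were 2706 (WT day 7), 424 (DKO-labelled) and 2564 (difference). With DESeq2 they were 409 and 1212 in WT cells for sphingosine and for the comparison of the compounds, 338, 29 and 271 in DKO-labelled cells, 139 for the sphingosine difference and 35 for doxycycline in DKO-labelled cells. With the length offset they were 1153 (undifferentiated), 2217 (myriocin, WT day 19), 2 (sphingosine, DKO-labelled), 27 (compounds, DKO-labelled), 849 (doxycycline, WT day 7), 2 (doxycycline, DKO-labelled) and 768 (doxycycline difference). For sphingosine in DKO-labelled cells RLE factors gave 3 and leaving out mitochondrially encoded genes 3, and for doxycycline in DKO-labelled cells the day 9 libraries alone gave 0 by edgeR. The cause was not tested, except that the filter changes the genes tested.

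With each library left out in turn, where fewer libraries alone can change the count, counts ranged from 689 to 10304 for undifferentiated cells, 5019 to 7785 for the genotypes at day 9, 1395 to 2949 for myriocin in DKO-labelled cells at day 6 and 1968 to 5436 in WT cells at day 19. In WT cells the ranges were 1295 to 4133 for 1-deoxysphingosine, 0 to 868 for sphingosine and 66 to 1659 for their comparison, and in DKO-labelled cells 0 to 174 for 1-deoxysphingosine and 0 to 130 for the comparison. For the genotype differences they were 240 to 3000 (1-deoxysphingosine), 0 to 615 (sphingosine) and 279 to 1500 (doxycycline). For doxycycline itself they were 8 to 1770 (WT day 7), 951 to 3029 (WT day 9) and 0 to 3 (DKO-labelled). Camera called 315 of the 700 list tests with the preset correlation and 19 with an estimated correlation, and 27 and 0 of the COUP-TF sets. Over genes with a mean log2 CPM of at least 3 the correlations were 0.64 and 0.54 for 1-deoxysphingosine with doxycycline at days 9 and 7, -0.36 and 0.05 with myriocin at days 6 and 19, 0.36 for doxycycline at days 9 and 7, and -0.34 and -0.36 for these with myriocin at day 6. Replicate numbers did not pair all groups (r above 0.1 in 10 of 35 pairs, -0.37 to 0.55). Within a genotype (-0.25 to 0.55) pairing stays open. The replicate block gave sphingosine counts of 1 in DKO-labelled cells and 2 for the genotype difference. No other count moved by over 1.5 times. The median of all genes shifted by over 0.1 for day 9 against day 0 without the filter (-0.101) and for day 19 against day 9 with the offset (-0.104). Depth limits NR2F1 in undifferentiated DKO-labelled cells (3 counts).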

Other observations

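The tests in this part and the genes in it were chosen after the data were seen.

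Some genes were off in part of the libraries, at under 0.5 CPM in each of these and over 5 CPM in each of the others. NLRP2 (ENSG00000022556.15, chromosome 19, 54953130 to 55001142), an inflammasome family gene, and ZNF682 were off in the 20 DKO-labelled libraries and on in the 24 WT libraries, with NLRP2 at 0 to 0.489 CPM and 21 to 138 CPM. Such genes may follow the edit or another difference of the lines, which genotype comparisons cannot tell apart. CHCHD2, a gene of a mitochondrial protein, and ZNF248 were off in the 14 WT libraries of days 7 and 9. CHCHD2 was at 0 to 0.135 CPM there, 57.3 to 127 CPM in WT libraries of days 0, 6 and 19, 71.8 to 103 CPM in DKO-labelled libraries of those days and 18.4 to 26.1 CPM in those of day 9. ZNF558 was low in WT libraries of days 7 and 9 alone (levels above). Off in the libraries of days 7 and 9 of both genotypes were AC079779.2, MT-TC, MT-TP and NEUROD2.

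For CHCHD2 and ZNF558, library preparation of the day 7 and 9 experiments is argued against by the lowest DKO-labelled day 9 library, at 18.4 CPM of CHCHD2, and a stage or experiment effect alike in both genotypes by the lowest of ZNF558, at 39.5 CPM. WT cells of another stock in those experiments may be the source, with 2 genes off in these libraries alone and 0 off in the DKO-labelled day 9 libraries alone. This cannot be told apart from an effect of the stage or experiment on WT cells alone, because no WT libraries of days 7 and 9 come from elsewhere. All genotype comparisons at day 9 (levels, responses and gene sets) have these libraries as the WT side. Day 9 against days 0 and 19 uses them too. All share this limit.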
